A study of Danio rerio with 6 samples.

How the data were processed

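Messenger RNA was measured in whole zebrafish embryos at 25 hours post fertilization (hpf) on 6 Affymetrix arrays, 3 of prdm1a mutants and 3 of wild type. Per the labels' protocols, embryos were sorted by phenotype, total RNA was isolated with Trizol, ribosomal RNA was reduced, and whole-transcript cDNA was amplified, fragmented and labelled with biotin. The number of embryos behind each RNA sample is not given in the sources used here.

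The deposited values are probe set intensities on a linear scale, made with MAS5 per the submitters' processing notes. Its version, scaling target and detection calls are not given in the sources used here. In the deposited intensities the mean signal after trimming 2% lay between 500.13 and 500.14 on every array, so a common scaling had been applied before deposit. Array medians lay between 132 and 148, and no 2 arrays held identical values. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.222.

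The table held 15617 probe sets. A platform annotation gave 10802 of them 1 gene symbol, 135 several and 4680 none. Through the RefSeq gene table of the GRCz12tu assembly, used for names and for the order of genes along chromosomes, 10718 symbols were matched and 1 was updated. Probe sets with several symbols or none stayed unnamed. No probe set was named prdm1a or prdm1b, so the level of the mutated gene, planned as a check of the labels, is not analysed here.

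Intensities were log2-transformed as deposited. After 115 control probe sets were set aside, the lowest 30% of the other 15502 by mean log2 signal (4651 probe sets, below 5.36, a signal of 41.1) were left out, and 10851 were tested, 8119 of them named and covering 7053 genes. Each was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend of the prior variance on level), with genotype as the only term and Benjamini-Hochberg adjustment over all tested probe sets at 0.05. The prior had 5.08 degrees of freedom.

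Before the data were examined, 19 gene lists were fixed for the tissues and pathways of the embryo. Each gene was read from its brightest named probe set, and lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The same lists were tested with an estimated correlation and with fry, which tests whether a list moves, on balance, in 1 direction. Member counts are given over all probe sets tested and adjusted over the list alone.

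The rule for genes named in the text was also fixed before the data were examined. It takes the 10 genes with the largest change in each direction among probe sets past the threshold whose brighter group reached the table's median level and whose arrays did not overlap between groups. It adds up to 4 members past the threshold from each list, or the 2 members with the smallest p where none passed. It further adds foxd3, tfap2a, sox10, crestin, isl1, smyhc1, prox1a, mylpfa, sox6, ctslb, he1a and dlx2a where measured. No value is given for sox6 and he1a, which no named probe set carried alone, or for ctslb, which lay below the filter. Genes named outside this rule are said to have been chosen after their values were seen.

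The fit was tested on simulated data for this comparison, with 200 of the 10851 probe sets changed in each of 10 draws. It recovered 56.4% of probe sets with a log2 fold change of 1 and 94.5% with a log2 fold change of 2, and 6.38% of its calls were false. A shift of 0.5 given to the fast muscle list was called in 10 of 10 draws, with 0.1 other lists called per draw. The simulated probe sets varied independently of one another, while the estimated correlation within the fast muscle list was 0.375 in the data. These list rates therefore do not carry over to the data. The simulated noise was normal, with variances taken from the same fit. The probe set rates therefore describe the fit under its own model and are not error rates of the calls in the data.

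Alternatives fixed in advance were quantile, median and cyclic loess normalization, offsets of 16 and 64 before the log, no filter and a filter of 50%, other variance models and array weights, the replicate number as a block, each array left out, other thresholds, a per-probe-set test without shared variance, and other list tests. Adjustment for the 3' over 5' signal ratio of the gapdhs or the actc1b control probe sets was added after the data were seen. For a value past the threshold neither here nor under an alternative, a change of sign was not counted as a change. Replicates are separate samples by their labels, which do not say that they came from separate clutches, so p-values measure only the spread between these samples. Figures were drawn with matplotlib 3.10.9.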

Results

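The 6 arrays compared embryos labelled as prdm1a mutants with embryos labelled as wild type at 25 hpf (n = 3 per genotype). The gene prdm1a encodes a zinc finger transcription factor known to act in slow muscle, neural crest and sensory neuron fates. The comparison asks which transcripts differ in level between these groups, without a value for prdm1a itself. Arrays of the mutant correlated at 0.967 to 0.969 with one another, arrays of the wild type at 0.948 to 0.976, and arrays of different genotype at 0.923 to 0.949, over probe sets tested. The first principal component held 44.5% of the variance and separated the genotypes. The second held 21.5% and spread the wild-type arrays, from -31.5 for replicate 1 to 34.8 for replicate 3.

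In the mutant, the slow muscle genes smyhc1 and myl13 and the neural crest genes crestin and sox10 fell, while 5 fast muscle genes and the secretory gland gene agr2 rose. The slow myosin heavy chain smyhc1 was 7.89-fold lower, and agr2, which encodes a protein disulfide isomerase of secretory cells, was 4.87-fold higher. Crestin, a marker of migrating neural crest, was 3.68-fold lower. Over the embryo, 368 of 10851 probe sets (3.39%) changed past an adjusted p of 0.05 (limma, Benjamini-Hochberg), 167 higher and 201 lower in the mutant. The 258 of these that carried a gene name stood for 124 genes higher and 129 lower. Of all 368, named or not, 258 changed at least 2-fold (115 higher, 143 lower). All 368 were separated between genotypes in every array. Over all tested probe sets 2929 (27%) were separated so, where chance gives 10%. Without single arrays the counts higher and lower were 79 and 131 (without mutant replicate 1), 77 and 123 (mutant replicate 2), 54 and 116 (mutant replicate 3), 169 and 160 (wild type replicate 1), 47 and 67 (wild type replicate 2) and 258 and 203 (wild type replicate 3), so which direction held more calls depended on the wild-type arrays.

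A ratio used as a sign of RNA quality moved with genotype, with every mutant array below every wild-type array. The 3' over 5' signal ratio of the actc1b control probe sets was 33.6 ± 6.60 in the mutant and 69.1 ± 20.3 in the wild type (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow). That of gapdhs was 6.0 ± 2.37 and 11.8 ± 2.66 (SD, n = 3 each; exact permutation p = 0.1). The ratios of the spiked bacterial controls gave exact permutation p-values of 0.3 to 1. With the gapdhs ratio as a covariate, chosen after the data were seen, 44 probe sets passed, 35 of them among the 368, and with the actc1b ratio 26 passed, 22 of them among the 368. Among genes named by the rule, copb2, spint1b, pdcl3, agr2, hnrnpa0a and smyhc1 passed in both fits.

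**Figure D1:**
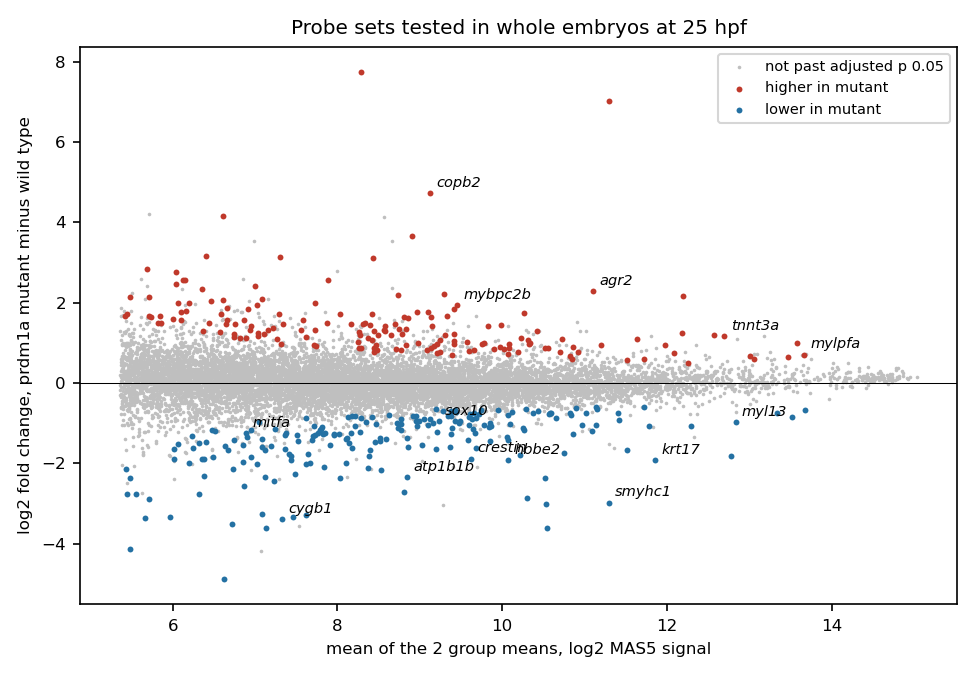
Log2 fold change (prdm1a mutant minus wild type) against the mean of both group means in log2 MAS5 signal, 1 point per probe set tested. Red points (167) were higher and blue points (201) lower in the mutant past an adjusted p of 0.05, and smyhc1 and agr2 are among the labelled genes.

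The slow muscle genes that passed fell and the fast muscle genes that passed rose. Of 7 slow muscle genes measured, smyhc1 and the light chain gene myl13 fell, and 5 did not pass (2 lower adjusted over the list alone). The log2 signal of smyhc1 was 9.80 ± 0.21 in the mutant and 12.78 ± 0.07 in the wild type (SD, n = 3 each), a log2 fold change of -2.98 (SE 0.14, limma adjusted p = 2.8e-05). That of myl13 was -0.98 (SE 0.14, limma adjusted p = 0.00824). The slow fiber transcription factor prox1a was at 0.57, which did not pass (limma adjusted p = 0.388). The list had a median log2 fold change of -0.20 and a mean of -0.74, and passed camera (adjusted p = 0.0252). It did not pass at an adjusted p = 0.553 with an estimated correlation.

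Of 21 fast muscle genes, 5 rose and 16 did not pass, while adjusted over the list alone 15 rose and 1 fell. The fast myosin-binding protein gene mybpc2b rose by a log2 fold change of 1.94 (SE 0.21, limma adjusted p = 0.00233). The troponin T genes tnnt3a (1.16) and tnnt3b (1.19), the light chain gene mylpfa (0.71) and the tropomyosin gene tpma (0.60) rose as well, tnnt3b having been chosen after its values were seen. The median log2 fold change of the list was 0.57, and 20 of 21 members were above 0 (camera adjusted p = 4.2e-08; adjusted p = 0.553 with an estimated correlation; fry adjusted p = 0.0757). Without mutant replicate 1 the median was 0.34. The 3' over 5' ratios given above moved with both muscle lists. The fast muscle list still passed camera with the gapdhs ratio (adjusted p = 1.6e-11; adjusted p = 0.601 with an estimated correlation) and the actc1b ratio as a covariate (adjusted p = 0.00297; adjusted p = 0.678 with an estimated correlation). The slow muscle list no longer passed with the gapdhs ratio (adjusted p = 0.223) or the actc1b ratio as a covariate (0.105), nor without mutant replicate 3 (0.0512) or wild type replicate 3 (0.0621). Calls ended for myl13 without wild type replicate 2 (limma adjusted p = 0.0555), for mylpfa without mutant replicates 1 or 3 or wild type replicate 2 (up to 0.0824), for tnnt3b without mutant replicates 1 or 3 or wild type replicates 1 or 2 (up to 0.155), and for tpma after median centring (0.0734) or without any array but wild type replicate 3 (up to 0.135). Without the variance trend mylpfa, tnnt3b and tpma did not pass (0.0775, 0.0921 and 0.112), nor did tnnt3b in the robust fit (0.0511). With the gapdhs and actc1b ratios as covariates, myl13 (limma adjusted p = 0.247 and 0.123) and tnnt3a (0.0686 and 0.2525) did not pass. Nor did mylpfa (0.334 and 0.480), tpma (0.313 and 0.651) or tnnt3b (0.266 and 0.467). The mybpc2b change passed with the gapdhs ratio (0.0319) and not with the actc1b ratio (0.161).

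**Figure D2:**
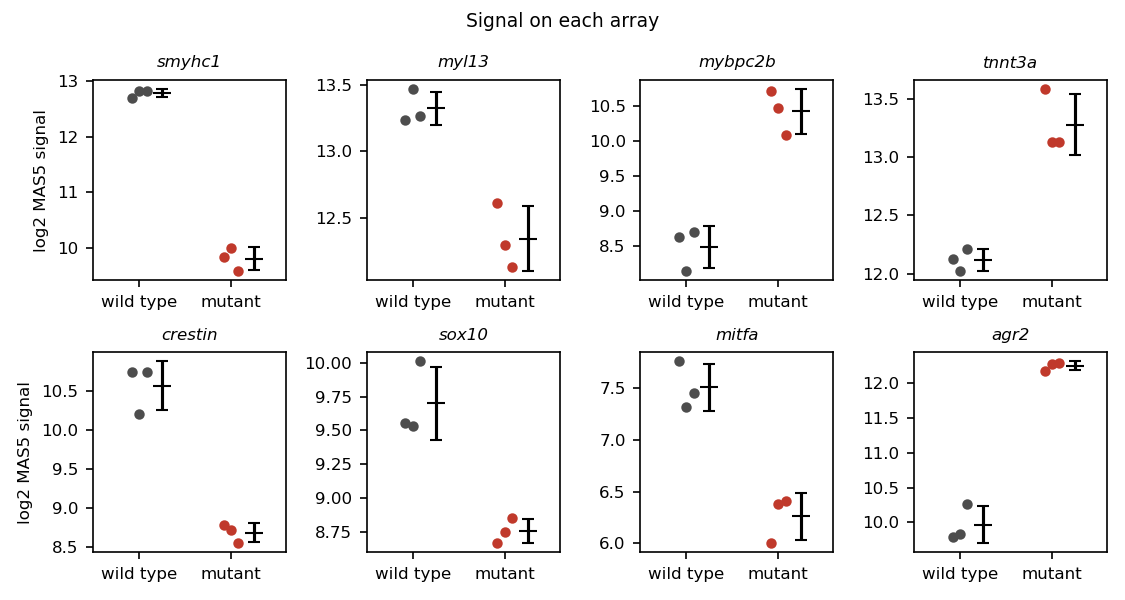
Log2 MAS5 signal of 8 genes on each array, with the mean and SD of 3 arrays beside the points. Axes differ between panels and do not start at 0, and in each panel the genotypes do not overlap.

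Among neural crest specifiers, crestin and sox10 fell and the other 14 of 16 measured genes did not pass (2 lower adjusted over the list alone). The log2 signal of crestin was 8.69 ± 0.12 in the mutant and 10.57 ± 0.31 in the wild type (SD, n = 3 each), a change of -1.88 (SE 0.18, limma adjusted p = 0.00124). The transcription factor gene sox10, which acts in pigment and glial lineages, changed by -0.95 (SE 0.18, limma adjusted p = 0.0227). The early specifiers foxd3 (-0.41, limma adjusted p = 0.444) and tfap2a (-0.14, limma adjusted p = 0.524) did not pass. The list did not pass camera (adjusted p = 0.439). Of 9 pigment cell genes, mitfa, the regulator of melanocyte fate, fell by 1.25 on the log2 scale, and the melanosome gene pmelb rose by 1.13 (limma adjusted p = 0.0273 and 0.0366). Adjusted over the list alone, 1 rose and 2 fell, and the list did not pass (camera adjusted p = 0.295). The sox10 call ended without any mutant replicate or wild type replicate 2 (limma adjusted p up to 0.0769), as did that of pmelb (up to 0.137), and that of mitfa also without wild type replicate 1 (up to 0.0867). Without the filter the adjusted p of pmelb was 0.0517. With the gapdhs and actc1b ratios as covariates the crestin change was -1.74 and -1.76, with limma adjusted p-values of 0.0686 and 0.142. The sox10 change was -0.91 and -0.43 (limma adjusted p = 0.319 and 0.605), that of mitfa -1.49 and -1.10 (0.204 and 0.444) and that of pmelb 1.08 and 1.3 (0.395 and 0.366).

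Read from the brightest probe set of each gene, none of 10 Rohon-Beard and sensory neuron genes passed in limma, over all probe sets or adjusted over the list alone. With an unadjusted p under 0.05 in limma, prph, which encodes the neuronal filament peripherin, was at -0.96 (adjusted p = 0.102) and the LIM homeodomain gene isl1a at -0.68 (adjusted p = 0.125). A dimmer prph probe set, chosen after its values were seen, fell by 1.90 on the log2 scale (limma adjusted p = 0.00629; 0.0506 without wild type replicate 2; 0.183 and 0.156 with the gapdhs and actc1b covariates). The list had a median log2 fold change of -0.31, with 8 of 10 members below 0 (camera adjusted p = 0.0928; adjusted p = 0.553 with an estimated correlation; fry adjusted p = 0.0257).

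In the hatching gland list, agr2 rose and the other 5 of 6 measured genes did not pass (1 higher adjusted over the list alone). The log2 signal of agr2 was 12.25 ± 0.06 in the mutant and 9.96 ± 0.27 in the wild type (SD, n = 3 each), a change of 2.28 (SE 0.15, limma adjusted p = 0.000123). The list did not pass camera (adjusted p = 0.188; adjusted p = 0.597 with an estimated correlation), and fry gave an adjusted p of 0.0388. In epidermis and ionocytes, the keratin gene krt17 (-1.93) and the sodium pump subunit gene atp1b1b (-2.34) fell and 14 of 16 did not pass, with limma adjusted p-values of 0.000659 and 0.00334. The embryonic globin gene hbbe2 fell by 1.91 on the log2 scale (limma adjusted p = 0.00194), and 14 of 15 erythroid genes did not pass. Counts adjusted over the list alone were the same for epidermis and for erythroid genes (2 and 1 lower). Camera gave adjusted p-values of 0.643 for epidermis and 0.670 for erythroid cells. With the gapdhs and actc1b ratios as covariates, atp1b1b (limma adjusted p = 0.0753 and 0.231) and hbbe2 (0.0729 and 0.0580) did not pass. The krt17 change passed with the gapdhs ratio (0.0360) and not with the actc1b ratio (0.0870).

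In the other tissue lists few members moved. The endothelial transcription factor gene fli1 rose by 0.88 among 7 endothelial genes. Of 19 yolk and liver genes, the fatty acid binding protein genes fabp2 (-0.74) and fabp1b.1 (-0.67) fell and ambp (0.98) rose. Of 21 genes of the p53 pathway and cell stress, jdp2b (1.48) rose and mdm4 (-0.81), a negative regulator of p53, fell. Adjusted over the list alone, 1 endothelial gene rose, 1 yolk and liver gene rose and 2 fell, and 3 stress genes rose and 1 fell. Camera adjusted p-values of these lists were 0.879, 0.690 and 0.191. Processing choices and single left-out arrays ended these calls. That of mdm4 ended after quantile normalization (limma adjusted p = 0.0522), cyclic loess (0.0533) or without the filter (0.0505), and that of fli1 after median centring (0.0519). Without the variance trend, mdm4, fli1, fabp2, fabp1b.1 and ambp did not pass (0.0775, 0.0618, 0.0837, 0.0999 and 0.0801). With single arrays left out, those of fli1 and mdm4 held only without wild type replicate 3 (limma adjusted p up to 0.161 and 0.172), those of ambp and fabp1b.1 also without wild type replicate 1 (up to 0.135 and 0.132), that of fabp2 ended without mutant replicates 1 or 3 or wild type replicate 2 (up to 0.115), and that of jdp2b without mutant replicate 3 or wild type replicate 2 (up to 0.115).

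No member passed in limma over all probe sets for the pharyngeal arches and cranial skeleton (24 measured), pectoral fin (15), myeloid cells (11), central nervous system (30), eye and lens (8), notochord and hedgehog pathway (18) and cell cycle (26). Camera adjusted p-values of these lists were 0.943, 0.476, 0.643, 0.943, 0.652, 0.215 and 0.0970. Adjusted over the list alone, 3 notochord genes and 1 cell cycle gene rose. The members with the smallest p were col2a1a (0.60) and itga5 (-0.97) for the arches, and1 (1.13) and meis3 (0.33) for the fin, and spi1b (0.68) and lyz (-0.84) for myeloid cells. They were stmn2a (-0.66) and fabp7a (0.81) for the nervous system, rx3 (-0.86) and crybb1 (1.33) for the eye, lamc1 (1.45) and col9a2 (0.77) for the notochord, and cdc6 (0.65) and mcm5 (0.42) for the cell cycle. None of these directions is a call: over left-out arrays crybb1 ran from 0.56 to 1.77 and lyz from -1.38 to -0.31, and with the actc1b covariate crybb1 was at -1.68. The arch gene dlx2a was at -0.45 (limma adjusted p = 0.334).

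Housekeeping genes passed as a list with no member past the threshold in limma. Their median log2 fold change was 0.16 over 17 genes, with 15 above 0 (camera adjusted p = 0.0216; adjusted p = 0.627 with an estimated correlation). Adjusted over the list alone 2 rose, and gapdh (0.59) and mob4 (0.65) had the smallest p. The list did not pass after quantile normalization (adjusted p = 0.277) or cyclic loess (0.177), with fry (0.0868) or with the mean of a gene's probe sets (0.131), nor without mutant replicate 2 (0.118) or wild type replicate 1 (0.0668).

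**Figure D3:**
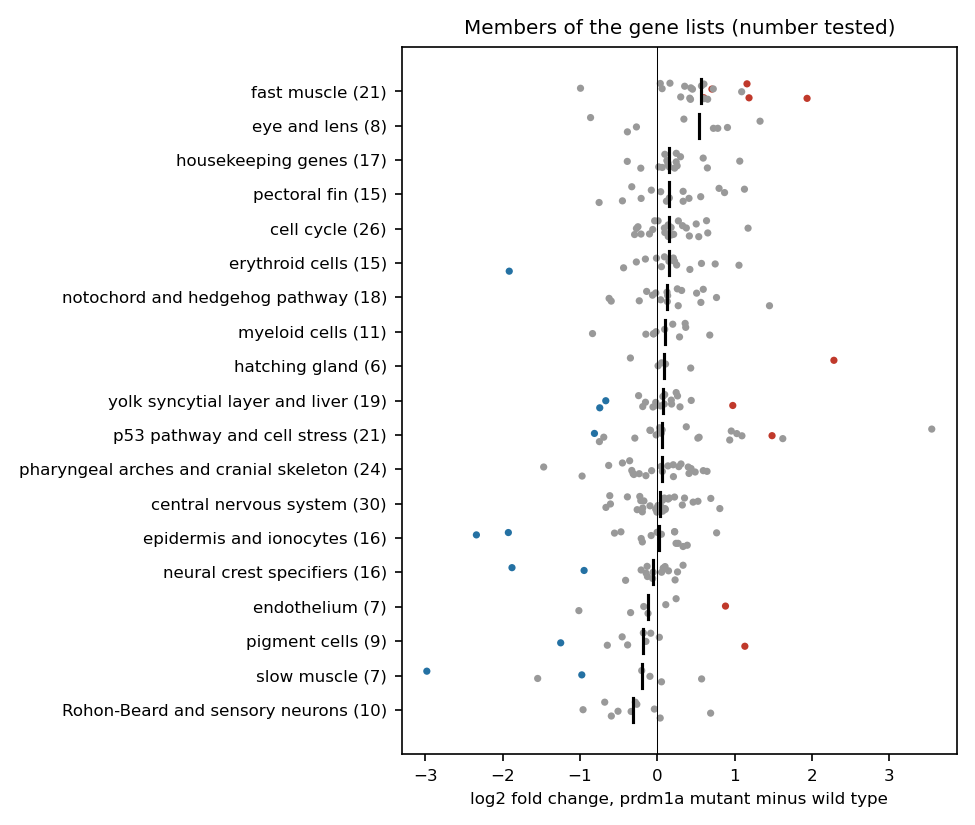
Log2 fold change (prdm1a mutant minus wild type) of each measured member of the 19 gene lists, with the number of members in parentheses. Red and blue points were higher or lower past an adjusted p of 0.05, grey points did not pass, vertical bars mark list medians, and the fast muscle list has the highest median (0.57).

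Among named genes that met the rule, the largest increases were those of copb2, a subunit gene of the COPI vesicle coat, at 26.6-fold (log2 fold change 4.73, SE 0.23, limma adjusted p = 2.8e-05), spint1b at 4.15, pdcl3 at 3.65, si:dkeyp-1h4.9 at 3.14 and tmem263 at 3.12. They were followed by the glycosyltransferase genes c1galt1a (2.85) and pofut1 (2.57), the kinase gene gsk3ba (2.46), anxa13l (2.34) and agr2. The largest decreases were those of rnf146 (-4.13), si:dkey-239j18.3 (-3.61), the globin family gene cygb1 (-3.39), mhc1zba (-3.35), ddit4 (-3.33), nradd (-3.28), slc39a13 (-3.25), hnrnpa0a (-3.02), smyhc1 and dkk3b (-2.88). The probe sets of rnf146, mhc1zba, ddit4 and dkk3b averaged signals of 10.7, 15.8, 19.8 and 19.4 in the mutant, and those of spint1b, c1galt1a, pofut1, gsk3ba and anxa13l 23.1, 19.2, 28.5, 28.0 and 36.4 in the wild type, under the filter level of 41.1, so these folds depend on dim values: with an offset of 64 before the log, rnf146 was 3.49-fold and mhc1zba 2.76-fold lower and spint1b 5.45-fold higher, against 17.6, 10.2 and 17.8. Other probe sets of copb2 were at 0.77 and 0.11, of hnrnpa0a at -0.36 and -0.26, of tmem263 at -0.15, of spint1b at 0.89, of pofut1 at 0.83, and of rnf146 at -2.40 and, in the opposite direction, 1.24, and none of these passed (limma adjusted p from 0.0644 to 0.794). Other probe sets of pdcl3 (2.05, limma adjusted p = 0.00497) and cygb1 (-3.33, limma adjusted p = 0.000775) passed. Calls ended for nradd without mutant replicate 3 or wild type replicate 2 (limma adjusted p up to 0.0659), for slc39a13 without mutant replicate 3 or any wild type replicate (up to 0.163), and for dkk3b without any array but mutant replicate 3 (up to 0.155). The slc39a13 call also ended with a 50% filter (0.0546), in the robust fit (0.105) and without the variance trend (0.0928), where dkk3b did not pass either (0.0663). Over left-out arrays the log2 fold change of slc39a13 ran from -3.86 to -2.19, and with an offset of 64 it was 3.96-fold lower, against 9.51.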

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

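The comparison of signals at the control probe sets, the test of muscle share and the list shifts with covariates below were chosen after the results were seen; the test against RNA length was planned before. The control probe sets for the 5' ends of actc1b and gapdhs, left out of the comparison of genes, were brighter in every mutant array than in every wild-type array. The actc1b 5' signal averaged 926.2 ± 215 in the mutant and 362 ± 88.1 in the wild type, and the gapdhs 5' signal 260.9 ± 110 and 137 ± 11.2 (SD, n = 3 each; exact permutation p = 0.1 for both, the smallest possible). At the 3' ends actc1b was also brighter in every mutant array than in every wild-type array (mutant over wild type ratio 1.27, exact permutation p = 0.1). The gapdhs 3' signal was not so separated (ratio 0.877, exact permutation p = 0.5). The actc1b 3' signal averaged 30168 in the mutant and 23829 in the wild type. The highest signals of the arrays ran from 29666 to 40015. Whether the actc1b ratio follows RNA quality or the level of actc1b itself cannot be told from these values.

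In the mutant 5 of 21 fast muscle genes were higher and 2 of 7 slow muscle genes, smyhc1 and myl13, lower. The slow genes actn2b (-1.55), tpm3 (-0.20), mb (-0.09), casq2 (0.05) and prox1a (0.57) did not pass. An effect of genotype on muscle and a larger share of muscle may both raise the fast list (mean shift 0.548, 95% interval 0.0638 to 1.03) and cannot be told apart by these values. From the slope on the gapdhs ratio within genotypes, RNA length predicted a fast muscle shift of -0.202 (95% interval -0.877 to 0.473), and on the actc1b ratio 0.03 (-1.10 to 1.17), while for the slow list, observed at -0.738, the gapdhs ratio predicted -0.394 (-0.520 to -0.267), in the observed direction. The bound written in advance, an upper limit below the observed 0.548, was met, but it left out the observed shift's own error, and with that error, a comparison chosen after the result was seen, the intervals overlap. With the gapdhs and actc1b covariates the fast list kept passing camera (adjusted p = 1.6e-11 and 0.00297; adjusted p = 0.601 and 0.678 with an estimated correlation), but its mean shifts of 0.75 (95% interval -0.13 to 1.63) and 0.51 (-0.79 to 1.81) had intervals that included 0, so RNA length and genotype cannot be told apart for it. For the slow list the shifts were -0.34 (-0.51 to -0.18) and -0.56 (-1.74 to 0.62), and smyhc1 passed in both fits at -2.69 and -2.89.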

How the results depend on the processing

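The covariates for RNA quality were chosen after the data were seen, all other alternatives before. Of 368 probe sets called in limma, array weights gave 1416, a threshold of 0.1 gave 811, and the planned test without shared variance gave 1 (1849 at an unadjusted p under 0.05); the gapdhs and actc1b covariates gave 44 and 26. The cause was not tested for the array weights; the covariates cost a degree of freedom and overlap with genotype. Leaving out single arrays gave 114 (without wild type replicate 2) to 461 (without wild type replicate 3) probe sets and 2 to 3 lists. Fits with fewer arrays have less power, which cannot give the rise to 461, and the cause of that rise was not tested. The other alternatives gave counts within 1.5 times of 368, from 258 without the trend to 450 with an offset of 64. Of 3 lists called by camera, 0 passed with an estimated correlation (0 also at an unadjusted p under 0.05), and of 3 called by fry, 1 was shared. With the replicate number as a block, 260 probe sets passed, 233 of them shared. That block ended the calls of mitfa, pmelb, tpma, fli1, fabp1b.1, ambp, mdm4, egr1, mybpc3, pdia7 and the probe set shared by he1.1 and he1.2 (limma adjusted p from 0.0606 to 0.0855). Deviations of same-numbered arrays correlated at 0.0613, 0.0523 and -0.0749, and those of differently numbered arrays at -0.125 to 0.0733. These values show no pairing by number, but with 3 arrays per genotype they cannot exclude one. Over named genes and alternative limma fits, 1236 values kept their side of the threshold, 236 lost their call and 28 gained one. Over lists and their alternatives the counts were 396, 14 and 6, and no call changed direction. Calls of smyhc1 and agr2 held in every alternative limma fit, with adjusted p up to 0.0111 and 0.0109. The only probe set called in the test without shared variance was higher in the mutant, so smyhc1 did not pass there. The prdm1a level has no value under any alternative. Dim signals limit large folds: with an offset of 64, rnf146 went from 17.6-fold to 3.49-fold lower, behind genes such as si:dkey-239j18.3, smyhc1 and hnrnpa0a, and copb2 from 26.6-fold to 17.0-fold higher. Of 10 splits of the 6 arrays, 1 gave as many probe sets (368; the highest other, 0), and 3 gave as many lists (3; the highest other, 3); 10 splits are too few for a share under 0.05.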

Other observations

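The lists and tests below, and the genes outside those named in the results, were chosen after the results were seen, and the lists were written after their called members were known, so they are not independent evidence. Of 28 genes measured for protein folding in the endoplasmic reticulum, 5 rose in limma, 23 did not pass and 11 were below 0. Those that rose were agr2 (2.28), the disulfide isomerase genes pdia3 (0.86) and pdia7 (0.67), prkcsh (0.88), which encodes a glucosidase subunit, and the thioredoxin family gene tmx2a (0.99). The list's mean shift was 0.30 (95% interval 0.22 to 0.39; camera adjusted p = 0.00213; adjusted p = 0.111 with an estimated correlation). The chaperone gene hspa5 was at 0.03 (limma adjusted p = 0.939). Without single arrays the calls of prkcsh, tmx2a and pdia7 ended (limma adjusted p up to 0.0769, 0.0997 and 0.164), as they did without the variance trend (0.0550, 0.0602 and 0.105) and for pdia7 after median centring (0.0708), and those of agr2 and pdia3 held there. With the gapdhs and actc1b covariates agr2 passed and pdia3 (limma adjusted p = 0.215 and 0.267), prkcsh (0.112 and 0.423), tmx2a (0.408 and 0.723, at 0.31 in the second) and pdia7 (0.342 and 0.409) did not. A probe set shared by the hatching enzyme genes he1.1 and he1.2 was lower (-0.84, limma adjusted p = 0.0444), a call that ended without mutant replicates 1 or 3 or wild type replicates 2 or 3 (up to 0.158) and without the variance trend (0.111) or with either covariate (-0.40 and -0.24, 0.602 and 0.784).

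Outside the measured members of the muscle lists, 4 genes of sarcomere proteins were picked by their values, with no count of such genes measured. The fixed slow list held myl10 only as an older symbol of myl13, and the fast list mylz3 only as an older symbol of myl1. Both lists were read from myl13 and myl1. The light chain gene myl10 (-1.83) and the myosin-binding protein gene mybpc3 (-1.10) were lower, and the light chain gene mylz3 (0.99) and the tropomodulin gene tmod4 (1.09) higher, in limma at adjusted p-values of 0.000769, 0.0417, 0.00597 and 0.00844. Calls ended without wild type replicate 2 for tmod4 (0.0546) and mybpc3 (up to 0.139, over 5 of 6 left-out arrays), and for mybpc3 without the variance trend (0.0626). With the gapdhs and actc1b covariates mylz3 (0.94 and 0.48), tmod4 (1.40 and 1.02) and mybpc3 (-0.83 and -0.46) did not pass, and myl10 passed with the first (-1.41, limma adjusted p = 0.0272) and not the second (-1.46, 0.123). Of 22 immediate early genes, egr1 (2.14), junbb (1.04) and ccn1 (1.29) rose (camera adjusted p = 0.000322; adjusted p = 0.179 with an estimated correlation), and the list's mean shift was 0.76 (95% interval -0.06 to 1.57). The egr1 call ended without any array but mutant replicate 2 (limma adjusted p up to 0.135) and with an offset of 64 (0.0611). Signals of egr1 averaged 21.2 in the wild type, under the filter level of 41.1, and the offset took its change from 4.40-fold to 1.90-fold. The junbb call ended without mutant replicates 1 or 3 or wild type replicates 1 or 2 (up to 0.105), the ccn1 call without any mutant replicate or wild type replicate 2 (up to 0.112), and both without the variance trend (0.0638 and 0.0592). With the gapdhs and actc1b covariates egr1 (0.97 and 1.75), junbb (0.76 and 1.34) and ccn1 (1.44 and 2.04) did not pass (limma adjusted p from 0.143 to 0.572). Of 5 egg coat genes, zp3.1 (-2.36) and zp2.6 (-2.27) fell (mean shift -1.11, 95% interval -1.64 to -0.57; camera adjusted p = 0.00263; adjusted p = 0.112 with an estimated correlation), and the zp2.6 call ended without mutant replicate 3 or wild type replicate 2 (limma adjusted p up to 0.0676). With the covariates zp2.6 did not pass (0.235 and 0.377), and zp3.1 passed with actc1b (0.0150) and not with gapdhs (0.0803). Another bright probe set of zp3.1 was at -1.04 and did not pass (limma adjusted p = 0.0808). Of the unnamed probe sets, 1 with a mean log2 signal of 7.78 in the wild type and 14.81 in the mutant was higher by a log2 fold change of 7.02. Another was at 4.41 and 12.15 (log2 fold change 7.74), the first of these under the filter level of 5.36, so its fold depends on dim values. A bright probe set with the same identifier apart from its suffix, named epcam, did not move with it (-0.19, limma adjusted p = 0.528). Another epcam probe set, at a mutant signal of 20.4 and so under the filter level of 41.1, was lower (-2.15, limma adjusted p = 0.0210). That call ended with single arrays left out (up to 0.0995) and with the gapdhs and actc1b covariates (0.202 and 0.533).

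Large changes were often seen by 1 probe set of a gene and not by its others. Of 41 genes changed at least 4-fold, 14 had another bright probe set, 18 probe sets in all, and for 15 of these the 95% interval did not overlap that of the called one, as sequence variants or transcript forms read by single probe sets would give, though the called probe sets were picked for their large change and 3 of the 18 passed in the same direction. The other probe sets showed a median of 14.1% of the log2 change, though for cygb1 the other probe set (-3.33) lay inside the interval. Most of the change would be shared if the whole transcript had changed. Picking the called probe sets for a large change lowers this share, and only the annotation ties them to the others. So a change of the whole transcript is neither shown nor excluded for these genes. A haplotype around prdm1a carried with the mutation stays open: of 39 genes changed at least 4-fold and placed on a chromosome, 3 lay among 327 measured genes on its own and 36 among 6678 elsewhere, an odds ratio of 1.71 (95% interval 0.335 to 5.45; Fisher's exact p = 0.428), too few to decide, while over all called genes, 12 of 327 against 237 of 6678, it was 1.03 (95% interval 0.522 to 1.87). Variants elsewhere in the genome that differ between the embryos of the genotypes may remain, and genotype effects on single transcript forms stay open.

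Of 7 light-induced genes measured, per2 (-2.15), cry-dash (-1.82) and tefa (-1.13) fell and all 7 were below 0, with a mean shift of -1.15 (95% interval -1.66 to -0.644; camera p = 1.08e-07; adjusted p = 0.112 with an estimated correlation). A shift of the whole circadian clock may also be involved and cannot be told apart here: the core clock list's mean shift over 13 genes was -0.158 (95% interval -0.555 to 0.238), with 4 above and 9 below 0, and clock genes of opposite phase can cancel in a mean. A difference in light exposure or collection time may give the same pattern as an effect of genotype, and the 2 cannot be told apart because neither light nor time of collection is in the labels. With the gapdhs covariate per2 passed at -2.25 (limma adjusted p = 0.0272), while cry-dash (-1.85, 0.113) and tefa (-1.03, 0.166) did not; with the actc1b covariate per2 (-2.02, 0.0803), cry-dash (-1.28, 0.298) and tefa (-0.80, 0.316) did not pass.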
